A study of Mus musculus with 2 samples.

How the data were processed

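Small RNA was sequenced from exosomes shed by mouse pancreatic islets. Exosomes are small membrane vesicles that cells release, and islets are the clusters of hormone-secreting cells in the pancreas. Per the labels' protocols, islets came from C57BL/6 mice on a normal diet with 4% fat (NCD) or a high-fat diet with 60% fat (HFD). They were kept in medium freed of serum exosomes. Vesicles were pelleted by ultracentrifugation from supernatants collected each day, total RNA was extracted and libraries were made with an NEBNext small RNA kit. The series holds 2 libraries, 1 per diet. How many mice or islet preparations stand behind each library is not given in the sources used here. No spread between animals or cultures can be estimated, so no p-value for a difference between the diets is given as a result. A test with assumed spreads was run only to match the authors' values and to see how their calls depend on the assumption.

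The values come from a single deposited table with 2083 entries, of which 677 carry mouse miRBase names and 1406 are predicted new miRNAs. Per the file headers, the table gives a raw count per library, a TPM value per library, and a p-value, an FDR and a log2 fold change for the comparison of the libraries. The authors' counts are whole numbers of reads per mature miRNA. They sum to 2417589 for NCD and 2020831 for HFD. The authors' TPM values are counts per 1000000 counts of the table, with no length scaling, as a comparison with the counts showed. The genome build was GRCm38 per the submitters' processing notes. The aligner, the miRNA caller, the counting of reads with several matches and the test are not given in the sources used here. The deposited log2 fold changes and p-values were matched on every entry by the exact test of edgeR 4.0.16 with TMM scaling and an assumed biological coefficient of variation of 0.1, with a largest difference in p of 6.55e-15. The authors' p-values therefore rest on an assumed and not a measured spread.

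From the counts, counts per 1000000 (CPM) were recomputed per library. The log2 ratio of HFD over NCD used a pseudocount of 1 CPM. Fold values without a pseudocount are given with a 95% exact (Clopper-Pearson) counting interval, conditional on the sum of both counts. The interval covers counting error only. The labels name no molecular identifiers, so copies made by PCR may be counted as separate reads. An entry was measured if the larger library held at least 10 counts. It was called higher or lower if the log2 ratio was at least 1 either way, a fixed rule of size and not a test. A fold against a library with 0 counts was computed against 3 counts in that library, about the most that a count of 0 allows, and is written as at least that fold. It leaves out the counting error of the other library, so the end of the exact counting interval nearer to 1, which is a lower fold, is given beside it.

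The 16 lists of miRNAs, the rule for the miRNAs named and the alternatives up to the counting interval below were fixed before the data were examined. The rule names the 10 most abundant known miRNAs of each library. It also names the 10 largest differences each way among known miRNAs with at least 100 counts in the larger library, all measured members of the miR-29 and islet endocrine lists, and from each other list the 2 most abundant members and the extremes of the ratio. The 16 lists hold 165 names and cover the miR-29, let-7 and miR-200 families, islet endocrine miRNAs, acinar pancreas, miRNAs reported higher or lower in islets of obese or diabetic rodents, the Dlk1-Dio3 and miR-17 to 92 clusters, a metabolic list called brown fat and insulin signalling, and markers of erythroid, immune, endothelial, mesenchymal, hepatic and striated muscle cells. Some names stand in 2 lists. Each list's median log2 ratio was ranked among the medians of 10000 random lists of known miRNAs of the same size, matched on expression decile. The random lists were not matched on GC content. The percentile describes these 2 libraries only. Lists with fewer than 3 measured members got no percentile.

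Hairpins were taken from GENCODE M21, which uses GRCm38, the build of the submitters' notes. Each hairpin was folded with RNAfold 2.7.2. The GC content of a miRNA was that of the 22 bases next to the terminal loop on its arm, starting 2 bases away from it. Of the known miRNAs with at least 100 counts, 96.1% had such a value. Base composition was examined after the ratios had been seen. GC content was first taken over the whole side of the hairpin that holds the arm. The narrower stretch next to the loop was adopted afterwards, when the results with both had been seen, because it lies closer to the mature miRNA. Results are given with both measures where they differ. Positions are those of the hairpin genes.

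Alternatives were median-of-ratios size factors (DESeq2 1.42.0), TMM factors, the deposited TPM, totals without the 5 most abundant miRNAs of either library, pseudocounts of 0.1 and 10 CPM, no count minimum or a minimum of 100, known miRNAs alone, and a call only if the whole counting interval lay beyond 2-fold. The median-of-ratios size factors came out as 1 for both libraries, so that alternative left the raw counts unscaled. Removal of the GC trend with either measure of GC content, merging of predicted entries with the same counts and other assumed coefficients of variation were added after the data were examined. Scripts were tested on simulated data with 200 changed entries and counting error only, in which 599 entries were measured. Of the entries made 4-fold higher 100% were called, of those made 4-fold lower 95.8%, and of the unchanged entries 5.71%. Among unchanged entries with at least 100 counts, 0% were called. The interval covered the true ratio for 94.3% of entries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.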

Results

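The comparison asked how the miRNA content of islet exosomes differs between mice on a high-fat diet and mice on a normal diet. The NCD library held 2417589 miRNA counts and the HFD library 2020831. At least 1 count was found for 522 known miRNAs in NCD and 599 in HFD, and at least 10 counts for 343 and 353. Predicted new miRNAs took 1.06% of the counts in each library. With a single library per diet, every difference below is between these 2 libraries and has no replicate check. A count of 0 allows up to 1.24 counts per 1000000 counts (CPM) in NCD and 1.48 CPM in HFD.

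Both libraries were dominated by a few miRNAs, and the same 3 led in each. miR-122-5p, the main miRNA of hepatocytes, took 32.1% of the NCD counts (95% exact binomial interval 32.1 to 32.2) and 24.2% of the HFD counts (24.1 to 24.3). miR-148a-3p, abundant in the exocrine pancreas and the liver, took 9.97% in NCD and 22.1% in HFD. miR-375-3p, the most characteristic miRNA of islet endocrine cells and a regulator of insulin secretion, took 8.18% and 8.33%. The next ranks went to miR-486b-5p and miR-486a-5p, which are abundant in red blood cells, and to miR-423-5p. Together the 10 most abundant miRNAs held 77.3% of the NCD counts (77.3 to 77.4) and 73.6% of the HFD counts (73.6 to 73.7). Their other members included let-7a-5p (3.40% and 1.99%), let-7f-5p (1.79% and 1.92%) and miR-99a-5p (1.70% and 2.35%). let-7b-5p ranked among the first 10 in NCD alone (2.43%) and miR-25-3p in HFD alone (1.43%). The hairpins of miR-486a and miR-486b lie on opposite strands of the same interval of chromosome 8 and share a stretch of 22 bases in the arm that gives the 5p miRNA. The split of reads between miR-486a-5p and miR-486b-5p is therefore uncertain.

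Known miRNAs with a 2-fold difference were more often higher than lower in HFD. Of 387 measured known miRNAs, 98 were at least 2-fold higher, 37 at least 2-fold lower and 252 within 2-fold. Their median log2 ratio was 0.33, so a list median near that value, or ratios above 1 alone, do not set a list below apart. With median-of-ratios size factors in place of the total count the split was 78 higher and 52 lower. These factors came out as 1 for both libraries, so they compared the raw counts with no correction for totals that differ by 1.20 times. Among the 207 known miRNAs with at least 100 counts, 40 were higher and 11 lower, against 31 and 19 with median-of-ratios size factors and 33 and 16 with TMM factors. Predicted entries leaned the other way, with 66 higher and 122 lower of 307, or 44 and 73 of 221 once entries with the same pair of counts were merged. Over all 694 measured entries 164 were higher and 159 lower. For 93 and 72 of all entries the whole counting interval lay beyond 2-fold. Among known miRNAs with at least 100 counts, the median shift of the log2 ratio relative to the values given here was -0.26 with median-of-ratios size factors and -0.15 with TMM factors. With a pseudocount of 10 CPM, let-7k, miR-1306-3p, miR-154-5p, miR-216a-5p, miR-29c-5p, miR-377-3p, miR-802-3p and miR-96-5p, given below, came within 2-fold. In the authors' deposited table, 374 entries had an FDR under 0.05, with 172 higher and 202 lower in HFD. Of these 374, 172 had 0 counts in a library and 74 had fewer than 10 counts in both.

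The highest ratio among known miRNAs with at least 100 counts was that of miR-1a-3p, a striated muscle miRNA, with 341 CPM in NCD and 7084 in HFD. It was 20.8-fold higher in HFD (counting interval 19.4 to 22.3). Its hairpins are Mir1a-1 on chromosome 2 (180389048 to 180389124, plus strand, GRCm38), outside any host gene on that strand, and Mir1a-2 on chromosome 18 (10785481 to 10785552, minus strand), in an intron of Mir133a-1hg. miR-101b-3p followed at 15.7-fold (11.3 to 22.5), from 15.7 to 247 CPM. Its hairpin lies in an intron of Rcl1 on chromosome 19 (29135279 to 29135375). miR-486a-3p was 8.12-fold higher (6.75 to 9.85), whereas the 5p arm of the same hairpin had a ratio of 0.741. miR-335-5p, encoded in an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), was 7.18-fold higher (4.68 to 11.4). It is the rarer arm, with 25 and 150 counts, and the more abundant 3p arm had a log2 ratio of only 0.24. miR-206-3p, a skeletal muscle miRNA, was 6.78-fold higher (5.78 to 7.99). The other 5 of the 10 largest ratios were those of miR-374b-5p at 4.74-fold, miR-192-5p at 4.65-fold, miR-122-3p at 4.50-fold, miR-690 at 4.34-fold and miR-203-3p at 4.17-fold. With the arm GC trend described last removed, the log2 ratio of miR-1a-3p was 3.63 in place of 4.37, and that of miR-335-5p 1.90 in place of 2.73. The ratio of miR-374b-5p was also lower by over 1.5 times, and that of miR-486a-3p higher by over 1.5 times, at a log2 ratio of 3.73.

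The miRNAs lower in HFD differed by smaller factors. miR-296-3p had 48.4 CPM in NCD and 7.92 in HFD, and was 6.11-fold lower (3.61 to 11.0). Its hairpin is on chromosome 2 (174267047 to 174267125, minus strand). miR-193b-5p was 2.97-fold lower (2.47 to 3.59), miR-760-3p 2.60-fold lower and miR-574-5p 2.38-fold lower. The more abundant 3p arm of the miR-574 hairpin went the other way, with a log2 ratio of 0.74. miR-505-5p was 2.33-fold lower and miR-204-3p 2.13-fold lower. miR-423-5p, from an intron of Nsrp1 on chromosome 11 (77078064 to 77078172), was 2.17-fold lower (2.14 to 2.19), from 59627 to 27541 CPM. miR-1306-3p, from an exon of Dgcr8, was 2.06-fold lower. miR-3473b and miR-3473e were 2.45-fold and 2.32-fold lower, but their hairpins share a stretch of 18 bases, so reads between them may be split. After removal of the trend with GC content described last, miR-204-3p and miR-1306-3p came within 2-fold with either measure of GC content. miR-423-5p and miR-760-3p did so with the GC content of the arm but not with that of the whole hairpin side, and miR-574-5p the other way round. The log2 ratio of miR-296-3p was -1.73 in place of -2.47 with the arm GC trend removed.

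**Figure D1:**
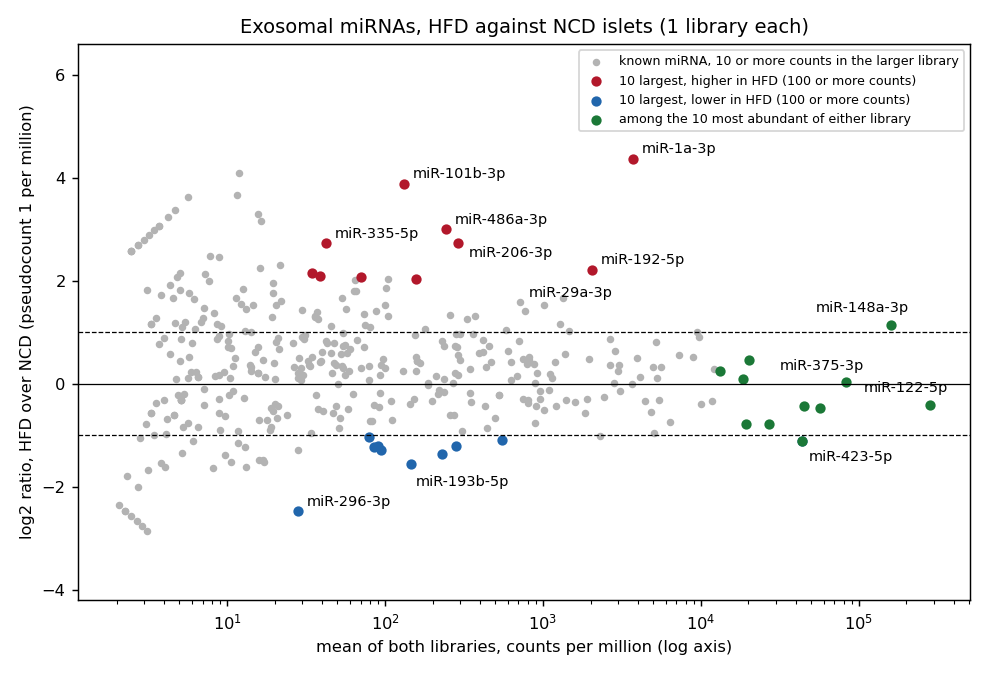
Log2 ratio of HFD over NCD (pseudocount 1 CPM) against the mean of both libraries in CPM on a log axis, with a point for each of the 387 measured known miRNAs. Red and blue points are the 10 largest differences each way among miRNAs with at least 100 counts, green points are among the 10 most abundant of either library (miR-423-5p is in both sets and drawn green), and dashed lines mark 2-fold; miR-1a-3p stands highest at 20.8-fold.

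miR-29a-3p, the abundant member of the miR-29 family, which represses the monocarboxylate transporter Slc16a1 in beta cells, was 3.02-fold higher in HFD (2.79 to 3.27). It had 861 counts in NCD and 2172 in HFD, or 356 and 1075 CPM. Its hairpin is on chromosome 6 (31062660 to 31062747, minus strand), outside any host gene on that strand. The other family members were rare. miR-29b-3p had 14 and 24 counts, a ratio of 2.05 (1.02 to 4.29), and was under the 2-fold rule once the pseudocount was added. miR-29c-5p had 6 and 14 counts, a ratio of 2.79 (1.01 to 8.86), and came within 2-fold with median-of-ratios size factors. miR-29c-3p had 14 and 9 counts, a ratio of 0.769 (0.294 to 1.91), which allows either direction. Of the 4 measured members 2 were higher and 0 lower, with a median log2 ratio of 1.06 and a percentile of 84.5 among random lists. That median was 0.45 with a pseudocount of 10 CPM. It was 0.30 with no count minimum, which adds the rarer miR-29b-1-5p (7 and 2 counts) and miR-29b-2-5p (8 and 3 counts), both with fewer counts in HFD and counting intervals that allow either direction. In the authors' deposited table miR-29a-3p had a log2 fold change of 1.44.

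Of 9 measured islet endocrine miRNAs 2 were higher and 0 lower, with a median log2 ratio of 0.36 (percentile 67.3). After removal of the trend with the GC content of the arm that median was -0.11, whereas it stayed above 0 with the GC content of the whole hairpin side. miR-375-3p had 81756 and 83261 CPM, a ratio of 1.02 (1.01 to 1.03), and its log2 ratio was below 0 with TMM factors, with median-of-ratios size factors and with totals without the 5 most abundant miRNAs. miR-182-5p was 2.11-fold higher (1.82 to 2.46), and miR-96-5p of the same cluster had 6 and 26 counts, a ratio of 5.18 (2.09 to 15.4). miR-183-5p of that cluster had a ratio of 1.65 (1.47 to 1.85). miR-7a-5p had a ratio of 1.55, miR-7b-5p of 1.28 and miR-9-5p of 1.24, all of which turned below 1 once the trend with the GC content of the arm was removed, but not with that of the whole hairpin side. miR-184-3p had a ratio of 0.704 (0.662 to 0.747) and miR-204-5p of 0.898 (0.794 to 1.02). miR-182-5p came within 2-fold under each of the 3 other scalings.

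All 4 measured acinar pancreas miRNAs were at least 2-fold higher in HFD, with a median log2 ratio of 1.28 (percentile 96.8). miR-148a-3p went from 99722 to 220847 CPM, a ratio of 2.21 (2.20 to 2.23). miR-217-5p had a ratio of 3.59 (2.72 to 4.78), miR-216b-5p of 2.70 (2.16 to 3.40) and miR-216a-5p of 2.15 (1.21 to 3.93). The last 3 are encoded within a stretch of chromosome 11 from 28746191 to 28763835. miR-148a-3p came within 2-fold with median-of-ratios and TMM factors, and miR-216a-5p with all 3 other scalings. Epithelial miR-200 family members all had ratios above 1, with 2 of 5 past 2-fold and a median log2 ratio of 0.95 (percentile 92.7). miR-200a-3p was 2.07-fold and miR-200b-3p 2.04-fold higher, and miR-200c-3p had a ratio of 1.39. The first 2 came within 2-fold under other scalings and with the GC trend removed by either measure. The list's median was 0.55 with the arm GC trend removed and 0.86 with that of the whole hairpin side.

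Among markers of other cell types, all 4 measured striated muscle miRNAs were at least 2-fold higher, with a median log2 ratio of 2.72, or 2.44 with miR-133b-3p set to its fold against 3 counts (percentile 99.9). That median ran from just under 2 with a pseudocount of 10 CPM to 3.57 with 0.1 CPM, and was 3.38 with totals without the 5 most abundant miRNAs. miR-133a-3p had a ratio of 3.26 (2.41 to 4.44), and miR-133b-3p had 0 and 11 counts, at least 4.39-fold higher against 3 counts, with a counting interval from just over 3. Of 7 measured immune cell miRNAs 4 were higher and 0 lower, with a median log2 ratio of 1.11 (percentile 97.9). That median was 0.86 with median-of-ratios size factors, 0.97 with TMM factors and 0.80 with the arm GC trend removed. Removal of that trend also brought miR-142a-3p and miR-223-3p within 2-fold. miR-146a-5p, induced by inflammatory signalling, was 2.67-fold higher (2.48 to 2.88), and miR-142a-5p and miR-150-5p had ratios of 1.49 and 1.25, the first of which changed sign on the log2 scale with the arm GC trend removed. Among hepatic miRNAs, miR-192-5p was 4.65-fold higher (4.41 to 4.91) and miR-122-3p 4.50-fold higher (3.07 to 6.78), whereas miR-122-5p had a ratio of 0.753 (0.751 to 0.756). The hepatic median log2 ratio was 1.53 (percentile 99.9), with 2 of 4 members higher. Both measured endothelial miRNAs had ratios above 1. miR-126a-3p had 6341 and 12659 CPM, a ratio just under 2-fold (counting interval 1.96 to 2.04), and miR-126a-5p a ratio of 1.65. All 5 measured erythroid miRNAs were within 2-fold, with ratios of 1.87 for miR-451a, 0.741 for miR-486a-5p and 0.722 for miR-486b-5p. The last 2 changed sign on the log2 scale with the GC trend removed. The list's median log2 ratio of 0.21 (percentile 46.1) became -0.05 with median-of-ratios size factors. Of 9 measured mesenchymal and smooth muscle miRNAs 2 were higher and 0 lower, with a median of 0.43 (percentile 70.7). The most abundant, miR-10b-5p and miR-143-3p, had ratios of 1.08 and 1.19, both of which changed sign on the log2 scale with median-of-ratios size factors. miR-143-5p had 0 and 23 counts, at least 9.17-fold higher against 3 counts (counting interval from 6.88), and miR-214-3p had a ratio of 0.531. With median-of-ratios size factors and with TMM factors miR-214-3p was past 2-fold lower.

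let-7 was the family with the lowest median log2 ratio of the 16 lists, at -0.39 (percentile 1.54). Of 10 measured list members, which are 5p arms and let-7k, 2 were at least 2-fold lower and 0 higher. let-7a-5p had a ratio of 0.585 (0.579 to 0.592) and let-7b-5p of 0.581 (0.573 to 0.589), and the rare let-7k had 39 and 10 counts. let-7e-5p, the other member past 2-fold, was chosen after its values were seen. With median-of-ratios size factors let-7a-5p and let-7b-5p were also past 2-fold lower, at log2 ratios of -1.03 and -1.04. let-7a-5p was so too with the GC trend removed by either measure. All 14 measured entries named let-7, a group formed after the results were seen, include 3p arms but not miR-98-5p. Of these, 1 was higher and 2 lower, with a median log2 ratio of -0.11. let-7i-5p had a ratio of 1.41 (1.37 to 1.45), and let-7f-5p of 1.07, which turned below 1 with median-of-ratios and TMM factors. These miRNAs differ by few bases, so reads with an error can pass between them.

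Among miRNAs reported higher in islets of obese or diabetic rodents, all 7 measured members had ratios above 1 and 2 were past 2-fold, with a median log2 ratio of 0.67 (percentile 90.0). The median over all 387 measured known miRNAs was 0.33. With the arm GC trend removed the list's median was 0.32, and 0.61 with that of the whole hairpin side. miR-21a-5p had a ratio of 1.74 (1.70 to 1.79), miR-132-3p of 1.16 (0.703 to 1.92), which turned below 1 with median-of-ratios size factors as miR-143-3p did, and miR-802-3p had 0 and 11 counts, at least 4.39-fold higher against 3 counts, with a counting interval from just over 3. Of the 3 measured miRNAs reported lower, miR-203-3p was 4.17-fold higher (3.46 to 5.05) and 0 were past 2-fold lower, with the ratio of 0.704 for miR-184-3p the lowest and a median of 0.45 (percentile 64.5). The large imprinted Dlk1-Dio3 cluster on chromosome 12 had 6 members higher, 1 lower and 40 within 2-fold of 47 measured, with a median of 0.33 (percentile 42.8). Its abundant members miR-543-3p and miR-541-5p had ratios of 0.601 and 1.26, miR-154-5p had 0 and 17 counts, at least 6.78-fold higher against 3 counts (counting interval from 4.94), and miR-377-3p had 12 and 0 counts, at least 3.34-fold lower against 3 counts (from 2.32). The miR-17 to 92 and paralogous clusters had 3 of 10 members higher and 0 lower, with a median of 0.30 (percentile 47.1). All 3 reached 10 counts in HFD alone, and no member with at least 10 counts in NCD passed 2-fold. Besides miR-19b-3p they were miR-18a-5p (0 and 10 counts) and miR-19a-3p (4 and 11 counts, counting interval 0.975 to 14.2). miR-19b-3p had 6 and 61 counts, a ratio of 12.2 (5.28 to 34.4), against 1.18 for miR-25-3p, which turned below 1 with median-of-ratios size factors, and 0.924 for miR-92a-3p. In the brown fat and insulin signalling list 0 of 5 passed 2-fold. Its median was 0.01 (percentile 25.3) and was below 0 with median-of-ratios size factors, TMM factors and totals without the 5 most abundant miRNAs, and its members ran from 0.625 for miR-107-3p to 1.13 for miR-130a-3p, with miR-27b-3p at 1.01 and miR-27a-3p at 1.12. All 3 ratios above 1 turned below 1 with median-of-ratios size factors.

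**Figure D2:**
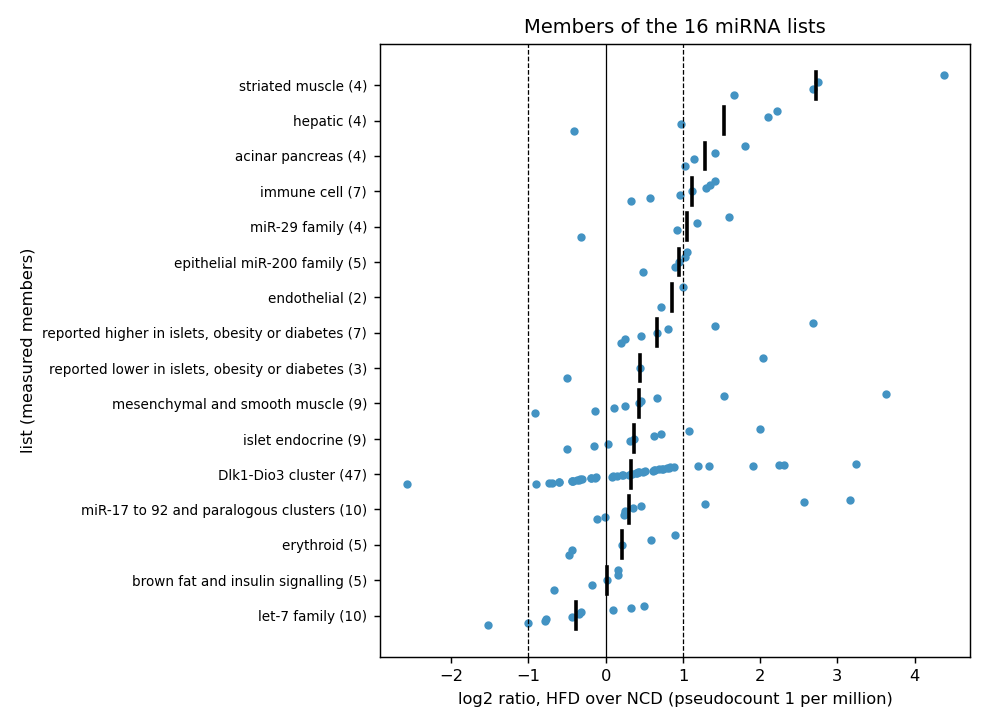
Log2 ratio of HFD over NCD (pseudocount 1 CPM) on the horizontal axis for each measured member (points) of the 16 lists, with the median as a black bar, the number of measured members in brackets and dashed lines at 2-fold. Striated muscle has the highest median at 2.72 and let-7 the lowest at -0.39.

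Base composition differed between miRNAs higher and lower in HFD. Across 199 known miRNAs with at least 100 counts, the log2 ratio decreased with the GC content of the miRNA arm, with Pearson's r = -0.38 and Spearman's rho = -0.38. Genes are not independent replicates, and the permutation p of 0.0001 for each, the smallest that 10000 draws can give, describes the association across miRNAs in these libraries. With the GC content of the whole hairpin side, the measure used first, r was -0.34 and rho -0.34, with the same p. All 4 correlations were computed after the ratios had been seen, and their p-values are given without adjustment for the number of correlations. The fitted ratio fell by 0.38 on the log2 scale (SE 0.07) per 10 percentage points of GC. The 50 miRNAs with a GC content of at most 43.2% had a median log2 ratio of 0.67, and the 38 with at least 56.8% had a median of -0.32. The first group had 17 members at least 2-fold higher and 2 lower, and the second 1 higher and 5 lower.

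**Figure D3:**
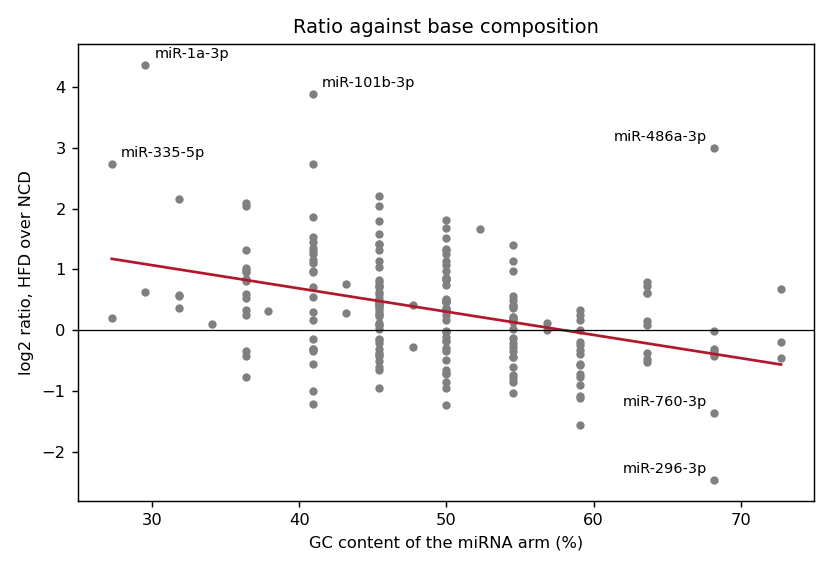
Log2 ratio of HFD over NCD against the GC content of the miRNA arm in percent, with a point for each of the 199 known miRNAs with at least 100 counts and a GC value, and the least-squares line in red. The line falls with GC content, and miR-486a-3p lies far above it at 68.2% GC.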

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

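Removal of the GC trend with either measure, merging of predicted entries and other assumed coefficients of variation were chosen after the data were examined. Each diet has 1 library, so no library could be left out in turn and no split of the libraries could be drawn. No paired analysis was possible because there is only 1 library per diet and the labels give no replicate numbers. Counting error limits the rare miRNAs: unchanged entries with few counts pass 2-fold by chance, and those with at least 100 counts did not in the simulation. The counts of 164 entries higher and 159 lower depended most on the treatment of low counts and on whether predicted entries were included. They were 66 and 37 with a pseudocount of 10 CPM, 457 and 388 with no count minimum, 42 and 23 with a minimum of 100 counts, 98 and 37 for known miRNAs alone, and 93 and 72 where the whole counting interval had to lie beyond 2-fold. Other scalings, the deposited TPM, a pseudocount of 0.1 and merging of predicted entries with the same counts gave counts within 1.5 times of these, although merging took the predicted entries alone from 66 higher and 122 lower to 44 and 73. The known miRNAs with a GC value that passed 2-fold were 91 higher and 30 lower, against 97 and 25 with the arm GC trend removed and 89 and 29 with that of the whole hairpin side. The number of entries detected was 1550 in NCD and 1647 in HFD, and 580 and 530 at 10 or more counts. The 3 most abundant miRNAs held 50.3% and 54.6% of the counts. All 148 alternative list medians lay within the interval of the median over the list's members. For lists of 7 or fewer measured members that interval ran from the lowest to the highest member. Their medians could therefore hardly leave it. Of the 148 medians 8 changed sign, all in the islet endocrine, erythroid and brown fat lists. Of the 38 named miRNAs at 2-fold or more, 0 changed sign under any alternative run for them. This was largely fixed in advance, since they were taken at a log2 ratio of at least 1 either way. Shifts from scaling and the GC trend were mostly smaller than that, and a larger pseudocount only draws ratios towards 0. The named miRNAs that came within 2-fold numbered 6 with median-of-ratios size factors, 5 with TMM factors, 4 without the 5 most abundant miRNAs, 8 with a pseudocount of 10 and 6 with the arm GC trend removed. With the GC content of the whole hairpin side 8 did, a different set that includes miR-148a-3p, miR-182-5p, miR-216a-5p and miR-574-5p but neither miR-423-5p nor miR-760-3p. The authors' 374 calls depend on the assumed coefficient of variation of 0.1: with 0.2 the same exact test of edgeR gave 189 and with 0.4 it gave 27, all among the 374. The 27 include 5 known miRNAs higher in HFD, which are miR-1a-3p, miR-101b-3p, miR-143-5p, miR-3470a and miR-6969-3p.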

Other observations

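The groups in the first 2 paragraphs, and the tests on muscle, miR-206, liver and blood sources, and on the counting intervals of the first pattern, were chosen after the results were seen. The bounds of the other tests on GC content and of thinning were set after the ratios, but before the results of these tests, had been seen. The measure of GC content reported first was adopted after its results were seen, so results with the earlier measure, over the whole hairpin side, are given too. Of 10 measured miR-30 members 5 were at least 2-fold higher in HFD and 0 lower. miR-30a-5p was 3.20-fold higher (counting interval 3.02 to 3.40), from 634 to 2029 CPM, and miR-30e-5p was 2.39-fold higher (2.14 to 2.68). miR-30d-5p, the most abundant member, had a ratio of 1.48 (1.45 to 1.51), and miR-30e-3p had a ratio of 0.864 (0.796 to 0.939). miR-378a-3p, encoded with the mitochondrial coactivator gene Ppargc1b, was 2.88-fold higher (2.70 to 3.08). All 4 measured miR-1843 members were past 2-fold, with miR-1843a-5p at 3.57-fold (2.70 to 4.78). These were picked among the families with high medians, and over all measured known miRNAs 98 of 387 were at least 2-fold higher. Other families had medians below 0, such as miR-130 at -0.85 over 3 measured members and miR-125 at -0.29 over 5.

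Among 89 hairpins with both arms measured, the rarer arm was at least 2-fold higher relative to the abundant arm in 26 and at least 2-fold lower in 12. Rare arms can pass 2-fold by counting error alone, and among the 33 hairpins whose rarer arm had at least 100 counts in the larger library the numbers were 8 and 2. The median difference was 0.23 on the log2 scale, with an interval over hairpins of -0.23 to 0.71, so no general shift towards the rarer arm was resolved. Among arms with over 100 counts in the larger library, miR-486a and miR-122 had the widest gaps. The rarer miR-122-3p went from 34 to 128 counts while miR-122-5p had a ratio of 0.753, so that the number of miR-122-5p counts per miR-122-3p count was 22836 in NCD and 3820 in HFD.

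The first pattern is the set of 2-fold differences among abundant miRNAs, 47 of which have a GC value. GC content tracks the ratio and accounts for 14.6% of its variance, and after removal of the linear trend 45 of all 199 miRNAs with a GC value were past 2-fold, 38 higher and 7 lower, made up of 36 of the 47 in the same direction and 9 others (43 with the earlier measure, with 36 of the 47 among them). This argues against a linear GC bias as the whole cause of the set. For 25 of the 47 the whole counting interval lay beyond 2-fold after removal (27 with the earlier measure), against 33 before it. The intervals after removal take the fitted trend as known and leave out its error. GC bias stays open for the other 22, although counting error alone already left some of them not clear of 2-fold. Among the 22 are 11 that came within 2-fold, such as miR-423-5p, whose log2 ratio went from -1.11 to -0.73. With the earlier measure of GC content miR-423-5p stayed past 2-fold. Of all 207 miRNAs with at least 100 counts, 35 had the whole counting interval beyond 2-fold, 30 higher and 5 lower, where counting error alone would give at most about 10.4, which argues against depth and counting error for these as far as reads are independent, while the intervals of the other 16 of the 51 differences reach under 2-fold, and thinning the NCD library to the HFD total, with 53 differences, could not decide because the totals differ by only 1.20 times. For all of the pattern, unequal ligation, unequal vesicle yield and the diet itself stay open, and a second library per diet would be needed to separate them.

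The second pattern is miR-1a-3p, whose log2 ratio was 3.63 after removal of the GC trend (counting interval 3.53 to 3.74) and 3.75 with the earlier measure of GC content. That interval takes the fitted trend as known and leaves out its error. Most of the difference remained with either measure, so the linear GC trend does not account for the whole of it. miR-206-3p held 7.08% as many counts in HFD, but miR-206 reads given to miR-1a-3p would be missing from that count, so this source stays open. All 3 other striated muscle miRNAs with at least 10 counts in the larger library were also past 2-fold, as muscle RNA in the HFD preparation would give. Of these, miR-133b-3p had only 0 and 11 counts. The rarer miR-208b-3p (6 and 1 counts) had a counting interval of 0.00433 to 1.64, which does not reach 2-fold higher. For miR-499-5p (7 and 8 counts) the interval was 0.433 to 4.43, which cannot show whether it rose. The list median was 2.18 with no count minimum. However, miR-1a-3p exceeded miR-133a-3p by 13.5 times in NCD and 86.2 times in HFD, so the muscle miRNAs did not keep a fixed ratio. A change in the islets of HFD mice was not tested and stays open.

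The third pattern is miR-122-5p as the most abundant miRNA of vesicles from cultured islets. The median log2 ratio of miR-122-3p, miR-192-5p and miR-194-5p lay 2.50 above that of miR-122-5p, with the 3 members from 1.381 to 2.625 above it. With the GC trend removed the median lay 2.16 above it (2.04 with the earlier measure). The 4 miRNAs thus did not keep a fixed ratio. However, the median member is miR-122-3p, from the same hairpin as miR-122-5p, so this gap cannot separate tissue sources. A single liver source of all 4, or one of miR-122-5p alone, stays open. Blood or serum vesicles are a candidate source, since miR-486a-5p, miR-451a and miR-423-5p are abundant too, but miR-16-5p, which red blood cells also carry, had only 128 and 185 CPM and miR-92a-3p 1141 and 1055 CPM, and the medium was described as freed of serum exosomes. The log2 ratios of 7 such miRNAs spanned 2.01 with no correction, and without miR-451a, which has no GC value, the other 6 spanned 1.64, and 1.36 with the GC trend removed, between the bounds of 0.75 for a single source and 1.5 for several. With the earlier measure of GC content the span of the 6 was 2.04, beyond the upper bound, so the outcome depends on the measure and a single blood source cannot be told apart from several sources here.

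Among predicted entries with at least 10 counts, 307 entries held 221 distinct pairs of counts, and 4 of the 51 with at least 50 counts shared both counts with another entry.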
